A study of Enchytraeus crypticus with 48 samples.

How the data were processed

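RNA from whole worms was measured on 48 one-colour (Cy3) oligonucleotide arrays, 4 to a slide on 12 slides, with 3 biological replicates in each of 16 groups. Per the labels, total RNA was labelled with the low-input one-colour kit with spike-in controls. Per the file headers, Agilent Feature Extraction 10.7.3.1 read each scan, and the processed signal in the deposited scanner files is an intensity that the authors' software background-subtracted and detrended within each array and did not scale between arrays. The deposited table of values holds the same processed signal rounded (largest difference 0.498%). The deposited files also give the median intensity of each spot and of its local background, and flags of 0 or 1 per spot. Slide and scan day were read from the file headers, and each slide held 3 or 4 groups.

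Each array held 45167 spots, of which 1417 were control spots and were left out. The remaining 43750 probes comprised 23177 named as contigs and 20573 named as single reads. The files pair no probe with a gene name or description. For that reason the 26 gene lists written before the data were examined could not be run, nor could their tests and alternatives. Between 30.0 and 61.8% of the probes of an array were well above background by the scanner's flag. The 75th percentile of signal was between 23.1 and 66.4, and no spot was saturated. The highest share of identical values between any 2 arrays was 0.00229%, and arrays of a group correlated at a median of 0.957 across probes, which are not independent replicates.

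The processed signal was log2-transformed and the 75th percentile of each array over all probes was subtracted. Spots marked as outliers were left out (620 among tested probes). A probe was tested if it was well above background on all 3 arrays of at least 1 group, which left 24011. One model of 16 group means was fitted across all 48 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation (32 residual and 3.43 prior degrees of freedom) and 2-sided tests. Benjamini-Hochberg adjustment was made over the tested probes within each of the 32 comparisons, and a probe was called at an adjusted p under 0.05. The 12 exposures were each compared with their control, acetone control with un-spiked soil, nano_ATZ with Gesaprim directly, and each formulation's change with that of ATZ as a difference of differences. EC50 was compared with EC10 within a material, and the change at 7 d with that at 3 d. With so few replicates the precision is limited by the number of arrays.

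The rule for naming probes was fixed before the data were examined. In each of the 12 exposures the called probes whose 3 exposed arrays all lay above, or all below, the 3 control arrays were ranked by size of change. In the other comparisons all called probes were ranked. Since the files pair no names, at most 2 that rose and 2 that fell were named per comparison. A lower bound on a fall or rise was given where 1 group was above background on no array. It holds for the main processing only and leaves out sampling error. Overlap between materials was set beside the product of the counts divided by the probes tested and beside 100 draws of residuals as unchanged groups against the same controls. Principal components were computed on the tested probes, and the share explained by each factor was tested by 10000 permutations.

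The steps were tested on simulated data with 50 changed probes at each of 4 sizes among 24011. The noise was drawn independently for each probe and array, without slide, day or replicate structure. The numbers of unchanged probes called can therefore understate false calls in the real data. For nano_ATZ EC50 against control at 3 d, 10, 60, 92 and 100% were recovered at 2-, 4-, 8- and 16-fold, with 7 unchanged probes called. For the difference between the changes by nano_ATZ EC50 and ATZ EC50 at 3 d, 0, 42, 66 and 92% were recovered, with 4 unchanged called. For nano_ATZ EC50 against EC10, 22, 92, 98 and 100% were recovered, with 12 unchanged called.

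The alternatives were normexp background correction (offset 50, on the median spot signal because the mean was not exported), quantile normalization, no filter, a filter to the 10676 probes above background on all 48 arrays, only the arrays of the comparison, slide or replicate number as a block, the deposited table of values, and leaving out each array in turn. Chosen after seeing the data were the 75th percentile over those 10676 probes, slide as a random block and leaving out the 4 arrays of slide 7. For every comparison, other splits of the same arrays were counted, all 10 where 3 arrays stood against 3 and 100 drawn splits otherwise.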

Results

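Transcript levels were measured in whole adult *Enchytraeus crypticus*, a small soil-dwelling oligochaete worm, after 3 or 7 days in soil with 1 of 3 atrazine materials. Atrazine is a triazine herbicide. The materials were a nanoformulation of atrazine (nano_ATZ), the pure active ingredient (ATZ, added in acetone) and a commercial formulation (Gesaprim). Each was given at its EC10 and its EC50, the concentrations that lower reproduction by 10 and 50%, so the materials were matched by effect and not by mass. Un-spiked soil was the control for nano_ATZ and Gesaprim, and soil with acetone was the control for ATZ. The 48 one-colour arrays made 16 groups of 3 biological replicates, so n = 3 per group throughout. Each array held 43750 probes, of which between 13137 and 27020 were well above background (median 20663.5), and no spot was saturated. The number of arrays limits the precision of every value. Of these probes, 24011 were tested. The files do not pair the probe IDs with gene names, so transcripts are given by the IDs of the files.

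Across the 12 exposures, 16 probes rose and 2 fell in every one. Of the 16, contig08852 had the largest minimum rise over the exposures. It went from a mean of -0.02 ± 1.20 (log2 signal relative to the 75th percentile of the array, SD) in control soil at 3 d to between 7.09 and 7.88 in the exposed groups of both days. Its rise lay between 102-fold and 239-fold (SE at most 0.46 log2 units), with 2 arrays in nano_ATZ EC10 at 3 d, where 1 spot was marked as an outlier. A second probe, contig07222, rose by between 4.86 and 6.86 log2 units, and contig17320 by between 3.06 and 8.83. With slide as a block contig17320 was called in 10 of the 12 exposures. Its controls were above background on 1 or 2 of 3 arrays, and its rise with nano_ATZ EC50 at 3 d was 7.14, or 3.22 after normexp. The falling probe contig16348 was above background on no exposed array, and its 12 falls were at least 1.96-fold to at least 33.4-fold. These lower bounds set the control mean against the exposed arrays' means, with each exposed array taken at its own signal or at the lowest signal among its well-above-background probes, whichever was higher. The bounds, here and below, hold for the main processing only and leave out sampling error. Over the alternatives the change of contig16348 shrank to -1.70 log2 units with nano_ATZ EC10 at 3 d and -0.95 with Gesaprim EC10 at 7 d. That of contig02942 shrank to -1.49 with nano_ATZ EC50 at 7 d. In the main processing, the changes of the other falling probe, contig02942, lay between -4.55 and -2.81 log2 units in 9 exposures. In the remaining 3, with no exposed array above background, its falls were at least 17.6-fold to at least 40.3-fold. These 5 probes were picked out for all 12 exposures after their values were seen.

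**Figure D1:**
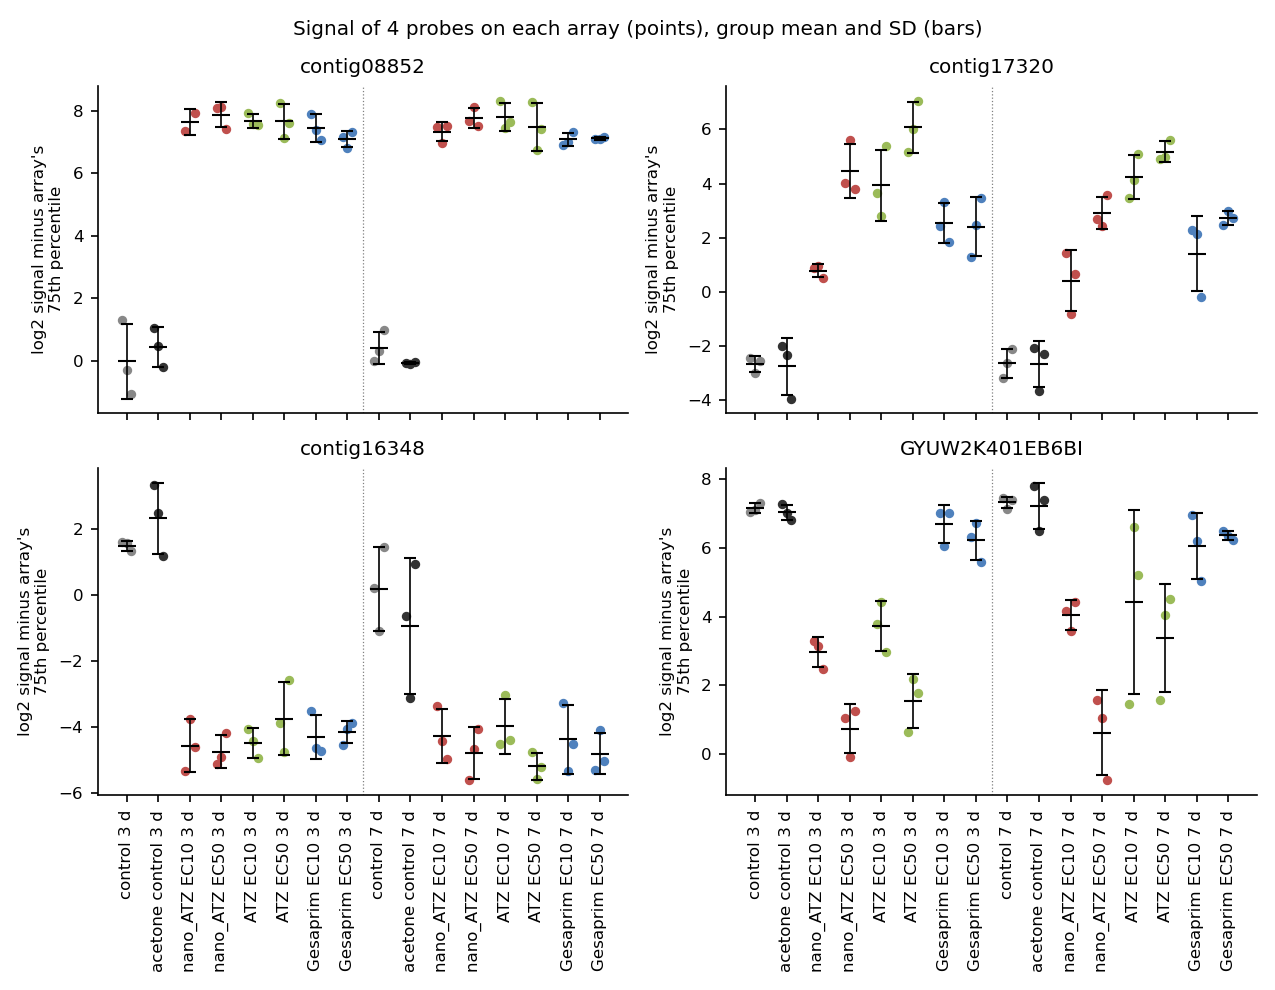
Levels of single probes in each group, as log2 signal relative to the 75th percentile of the array (y axis), by exposure and day (x axis). Points are arrays and bars are the mean ± SD. The exposed means of contig08852 lie between 7.09 and 7.88, and its control means lie between -0.07 and 0.44.

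In total, 1292 probes changed in at least 1 exposure (limma, adjusted p under 0.05), and 1042 of them in exactly 1. There were 46 probes that rose and 12 that fell in at least 6 exposures, while 2 probes rose in 1 exposure and fell in another. In 100 simulated draws of unchanged groups, the residuals of all 48 arrays, controls included, were shuffled over the groups. No probe was then called in the same direction in more than 2 exposures. The shuffling did not keep how slides, days and replicate numbers lay on the groups. Of the 1200 simulated comparisons, 52 called any probe, 11 called at least as many as the lowest observed count and 5 at least as many as the highest (mean 8.32, at most 2324). A count in 1 exposure, and so the 1042 probes called in exactly 1, can therefore include many false calls. With calls in so few simulated comparisons, the draws also say little about how often a probe repeats at the observed counts. With slide as a block, 10 probes rose in all 12 exposures and 0 fell in all, because contig16348 was then called in 9 and contig02942 in 11. The 18 common probes became 4 after normexp background correction and 9 when only probes above background on all 48 arrays were tested. On slides that held an exposed group and its control, contig08852 was higher in 10 of 10 comparisons, by at least 6.02 log2 units, and contig16348 lower in 11 of 11. Some of these comparisons share a control array.

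**Figure D2:**
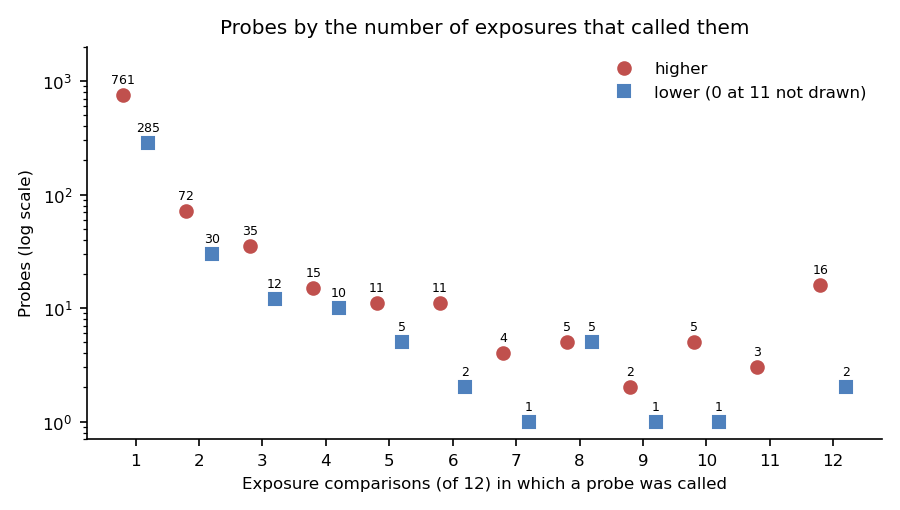
Number of probes (y axis, log scale) by the number of the 12 exposures in which a probe was called in one direction (x axis), for rises and falls. Of the 24011 probes tested, 23071 rose in none and 23657 fell in none (not drawn), and 16 rises and 2 falls were called in all 12.

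Does the nanoformulation change transcript levels against un-spiked soil? At 3 d, nano_ATZ EC10 raised contig07222 by 5.98 ± 0.54 (log2 ± SE, 62.9-fold, adjusted p = 5.85e-09) and GYUW2K402I47GJ by 3.62 ± 0.43 (adjusted p = 3.04e-06). A larger rise was that of contig08852, from -0.02 in control to 7.64. The rule for naming passed over it there because 1 of its exposed spots was marked as an outlier. In the same comparison contig16348 fell at least 32.1-fold, and GYUW2K401EB6BI fell by 4.18 ± 0.77 (adjusted p = 0.00374). At EC50, contig08852 rose by 7.90 ± 0.41 (239-fold, adjusted p = 1.34e-15) and contig17320 by 7.14 ± 0.68 (adjusted p = 1.85e-08), the latter from a control above background on 2 of 3 arrays (3.22 after normexp). Among the falls, GYUW2K401EB6BI fell by 6.41 ± 0.77 (84.9-fold, adjusted p = 1.07e-06) and contig16348 at least 17.9-fold. At 7 d, the leading rises at both concentrations were contig08852 (6.92 ± 0.41 at EC10 and 7.36 ± 0.41 at EC50) and contig07222 (5.91 ± 0.54 and 6.74 ± 0.54). With EC10 at 7 d contig19694 fell by 5.56 ± 0.98 (adjusted p = 0.00177) and contig02942 fell by 4.55 ± 0.53 (adjusted p = 2.59e-06), each above background on 1 of 3 exposed arrays. The change of contig19694 lay between -6.00 and -2.21 over the alternatives, was no longer called without slide 7 or with only the arrays of the comparison, and was -2.02 at its smallest within a slide. That of contig02942 lay between -4.64 and -1.43 over the alternatives and was no longer called with only the arrays of the comparison. With EC50 at 7 d GYUW2K401EB6BI fell by 6.69 ± 0.77 (103-fold, adjusted p = 4.34e-07), and contig02942 at least 26.4-fold. Each of the probes named by the rule had its 3 exposed arrays all above or all below its 3 control arrays, as the rule required. Of all probes tested, 17.8 and 13.5% did so at EC10 and EC50 at 3 d, and 5.67 and 20.4% at 7 d.

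The nano_ATZ counts were 67 probes at EC10 and 3 d (45 rose, 22 fell), 161 at EC50 and 3 d (122 and 39), 52 at EC10 and 7 d (34 and 18) and 236 at EC50 and 7 d (138 and 98). After normexp background correction the excess of rises turned, with 10 rises and 11 falls, 15 and 31, and 7 and 11 in the first 3. A block for slide made them 41, 172, 50 and 533. At 3 d, 1 slide held both groups at each concentration. The difference there was 6.38 for contig07222 and -4.63 for GYUW2K401EB6BI at EC10, and 9.16 for contig08852 and -6.27 for GYUW2K401EB6BI at EC50. At 7 d the within-slide difference of contig08852 was at least 6.02 at EC10 (2 slides). At EC50 (1 slide) it was 7.38, and that of GYUW2K401EB6BI was -5.53. The EC10 count at 3 d became 43 and 38 without control replicates 2 and 3, and 37, 34 and 40 without nano_ATZ replicates 1 to 3. The EC50 count at 3 d became 93, 88 and 104 without control replicates 1 to 3, and 73, 102 and 86 without nano_ATZ replicates 1 to 3. At EC50 and 7 d it became 132 and 91 without control replicates 1 and 3, and 124 and 99 without nano_ATZ replicates 2 and 3.

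**Figure D3:**
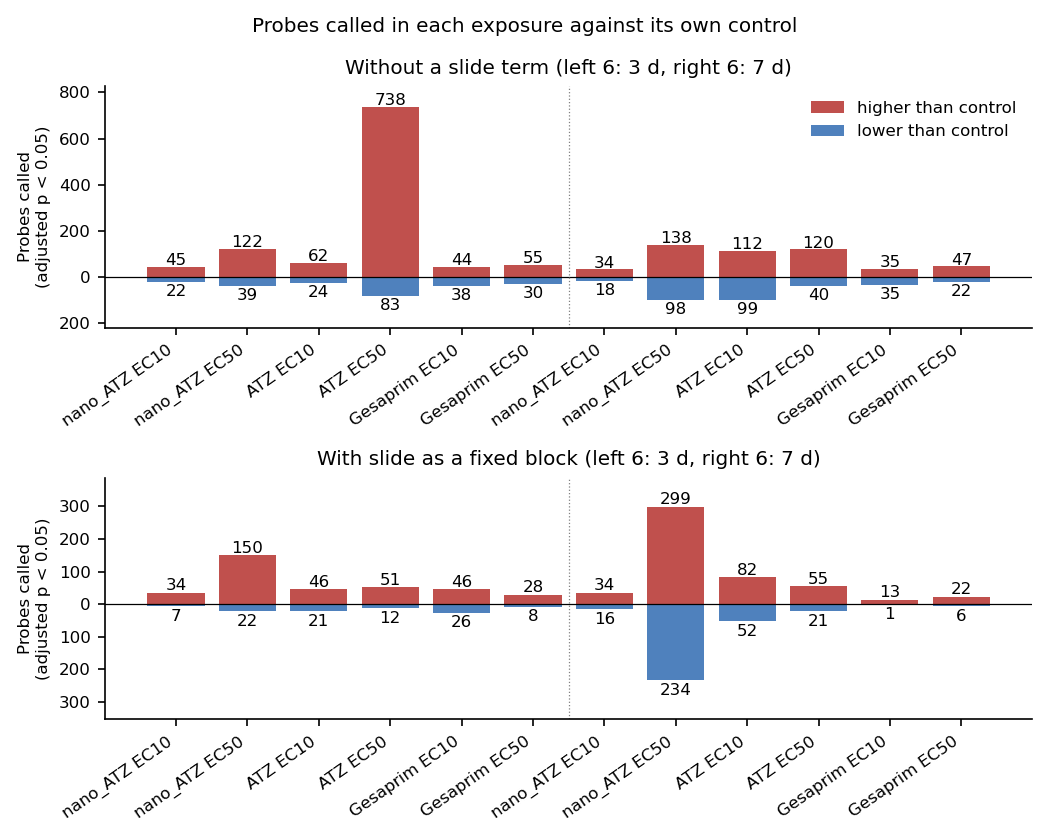
Number of probes called (adjusted p under 0.05) in each of the 12 exposures against its control, with rises and falls drawn in opposite directions. The upper panel has no slide term and the lower has slide as a fixed block. In the upper, ATZ EC50 at 3 d has the most, 738 rises and 83 falls, and nano_ATZ EC10 at 7 d the fewest, 34 and 18. In the lower, nano_ATZ EC50 at 7 d has the most, 299 and 234, and Gesaprim EC10 at 7 d the fewest, 13 and 1. ATZ EC50 at 3 d has 51 and 12 there.

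The commercial formulation was compared with the same un-spiked soil. Gesaprim raised contig08852 by 7.47 ± 0.41 at EC10 and 3 d (178-fold, adjusted p = 7.72e-15), 7.13 ± 0.41 at EC50 and 3 d, 6.68 ± 0.41 at EC10 and 7 d and 6.71 ± 0.41 at EC50 and 7 d (104-fold, adjusted p = 2.21e-13). The second rise was contig07222 in 3 of these comparisons, by 5.53 ± 0.54, 4.86 ± 0.54 and 5.71 ± 0.54 at EC10 and 3 d, EC10 and 7 d and EC50 and 7 d. At EC50 and 3 d it was contig17320, by 5.08 ± 0.68 (adjusted p = 1.74e-05), which was 2.07 and no longer called after normexp, nor called when only the arrays of the comparison were fitted. The fall of contig16348 was at least 18-fold and at least 14.8-fold at EC10 and EC50 at 3 d, and at least 7.96-fold and at least 15-fold at 7 d. At 3 d, contig26698 fell at least 3.14-fold with EC10 (adjusted p = 0.00902) and GYUW2K401C6JDK at least 15.3-fold with EC50 (adjusted p = 0.00418). At 7 d, GYUW2K401BS9YK changed by -4.44 ± 0.95 with EC10 (adjusted p = 0.0221) and by -4.66 ± 0.95 with EC50 (adjusted p = 0.0133), above background on 2 of 3 exposed arrays each time.

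Gesaprim changed 82 probes at EC10 and 3 d (44 rose, 38 fell), 85 at EC50 and 3 d (55 and 30), 70 at EC10 and 7 d (35 and 35) and 69 at EC50 and 7 d (47 and 22). The excess of rises turned in the first to 42 and 70 when scaled on the 75th percentile over probes above background on all arrays and 57 and 65 with slide as a random block, and in the last to 17 and 18 after normexp. A block for slide made the counts 72, 36, 14 and 28. It ended the calls of contig26698 (fitted change -3.34 ± 0.66 before and -2.61 ± 0.61 after, adjusted p = 0.0637) and GYUW2K401C6JDK (-4.56 ± 0.85 and -3.99 ± 0.99, adjusted p = 0.151). At 7 d it ended those of GYUW2K401BS9YK (-4.16 ± 1.32, adjusted p = 0.553 at EC10, and -3.99 ± 1.33, adjusted p = 0.204 at EC50). It also ended those of contig16348 at 7 d, whose fitted changes, no bounds since the exposed arrays were at background, went from -4.56 ± 0.72 to -3.80 ± 0.92 at EC10 (adjusted p = 0.220) and from -4.99 ± 0.72 to -3.97 ± 0.92 at EC50 (adjusted p = 0.106). At 3 d the within-slide difference of contig08852 was 7.68 at EC10 and 6.05 at EC50, and at 7 d no slide held both groups. The EC10 count at 3 d became 45, 42 and 34 without control replicates 1 to 3, 23 without Gesaprim replicate 1 and 424 without Gesaprim replicate 3. The EC50 count at 3 d became 55, 33 and 53 without control replicates 1 to 3, and 50, 47 and 204 without Gesaprim replicates 1 to 3. At 7 d, the EC10 count became 40, 37 and 46 without control replicates 1 and 3 and Gesaprim replicate 3. The EC50 count became 40, 109 and 33 without control replicates 1 to 3, and 38, 35 and 37 without Gesaprim replicates 1 to 3.

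The pure active ingredient was compared with acetone control. ATZ raised contig17320 and contig08852 most in all 4 comparisons. At 3 d, contig17320 rose by 6.69 ± 0.68 with EC10 (adjusted p = 6.29e-08) and 8.83 ± 0.68 with EC50 (adjusted p = 6.91e-11), from an acetone control above background on 1 of 3 arrays. At 7 d its rises were 6.91 ± 0.68 and 7.84 ± 0.68. After normexp background correction these 4 rises of contig17320 were 3.35, 5.10, 3.25 and 4.61, so their size depended on the background correction. The rises of contig08852 were 7.24 ± 0.41, 7.23 ± 0.41, 7.88 ± 0.41 and 7.57 ± 0.41 in the order EC10 and EC50 at 3 d, EC10 and EC50 at 7 d. At 3 d, contig16348 fell at least 33.4-fold with EC10 and at least 29.1-fold with EC50. The other named falls at 3 d were contig19694 with EC10 (-4.55 ± 0.98, adjusted p = 0.0181) and GYUW2K401EB6BI with EC50 (-5.50 ± 0.77, adjusted p = 2.03e-05). At 7 d, contig02942 fell at least 17.6-fold with EC10 and at least 40.3-fold with EC50, and GYUW2K401BS9YK at least 14.5-fold and at least 33.6-fold.

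ATZ EC50 at 3 d changed 821 probes (738 rose, 83 fell), with a median size of 1.22 log2 units, and 86 changed with EC10 (62 and 24). At 7 d, 211 changed with EC10 (112 and 99) and 160 with EC50 (120 and 40). The 112 and 99 turned to 27 and 73 after normexp, 148 and 222 after quantile normalization, 147 and 176 with slide as a random block and 152 and 200 with only the arrays of the comparison. With slide as a block, the 821 became 63 (51 and 12), 60 of them among the 821, while all 821 kept their sign, the median size went from 1.22 to 1.02 and the median SE over tested probes from 0.436 to 0.520. No slide held both ATZ EC50 and acetone control arrays at 3 d. The other blocked counts were 67 at EC10 and 3 d, 82 rises and 52 falls at EC10 and 7 d and 76 at EC50 and 7 d, with contig19694 at EC10 and 3 d no longer called (-4.28 ± 1.10 beside -4.55 ± 0.98, adjusted p = 0.136). Within slides, contig08852 was higher by 7.79 at EC10 and 3 d (1 slide), at least 7.69 at EC10 and 7 d (2 slides) and 8.33 at EC50 and 7 d (1 slide). The 821 became 74 after normexp background correction and 22 when only the arrays of the comparison were fitted. It became 189 without acetone control replicate 3, 475 without ATZ replicate 1 and 163 without ATZ replicate 3. The EC10 count at 3 d became 49 without ATZ replicate 3. At 7 d, the EC10 count became 83, 94 and 73 without acetone control replicates 1 to 3 and 78 and 102 without ATZ replicates 2 and 3. The EC50 count became 104, 84 and 72 without acetone control replicates 1 and 3 and ATZ replicate 3.

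Acetone itself was compared with un-spiked soil, the background against which the ATZ values stand. At 3 d, 1 probe was called, GYUW2K402HSE01, which was higher in acetone by 2.24 ± 0.37 (4.72-fold, adjusted p = 0.0142; 2.60 with slide as a block). Limma called 0 probes at 7 d, with 443 at an unadjusted p under 0.05, against 656 at 3 d. Where nothing changed, a share of 0.05 of the probes tested would still be expected at such a p, here and in all later counts. Both counts here lie under that share. Without any 1 of the 3 control arrays or acetone control replicate 3 the number called at 3 d was 0, without acetone control replicate 1 it was 2 and without replicate 2 it was 6.

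How far did the materials change the same probes? At matched effect concentration and day, 2 materials shared between 26 and 86 probes called in the same direction (median 39.5 over 12 pairs), and 0 in opposite directions. The number expected from the product of the counts, which takes probes as independent, was at most 3.88. The simulated unchanged groups shared 0, but only 52 of their 1200 comparisons called any probe. That 0 therefore says little about the overlap to expect at the observed counts. The nano_ATZ and Gesaprim comparisons used the same control arrays, which by itself gives related changes. For these pairs the covariance of changes across probes was 0.184, 0.198, 0.114 and 0.270, beside a simulated mean of 0.149, 0.153, 0.139 and 0.153. The draws, here and for the pairs with ATZ, did not keep how slides and days lay on the groups. The 3 control arrays are too few to be split, so part of the nano_ATZ and Gesaprim overlap may come from shared controls. Pairs with ATZ shared no array. Of the 12 pairs, 1 had a covariance above every simulated value, Gesaprim and ATZ at EC50 and 7 d (0.332 against at most 0.191).

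Direct comparison of nano_ATZ with Gesaprim asked whether the formulations differ. The largest difference was GYUW2K401EB6BI, which at EC50 stood at 0.74 ± 0.71 (SD) with nano_ATZ and 6.22 ± 0.57 with Gesaprim at 3 d, and at 0.63 ± 1.23 and 6.36 ± 0.13 at 7 d. The differences were -5.47 ± 0.77 (SE, adjusted p = 4.53e-04; -6.06 with slide as a block) and -5.73 ± 0.77 (adjusted p = 5.20e-05; -5.78). At EC50 and 3 d, contig12594 (2.82 ± 0.62) and contig09754 (2.47 ± 0.45) were higher with nano_ATZ, and GYUW2K402GM6N3 was lower while above background on only 1 of the 6 arrays. Both rises were no longer called after normexp or with only the arrays of the comparison, and contig12594 also not after quantile normalization or with no filter. With each of the 6 arrays left out in turn, contig12594 lost its call 4 times and contig09754 2 times. At EC50 and 7 d, contig09971 was at least 3.60-fold higher with nano_ATZ, GYUW2K402I0D5Q was higher but above background on 1 of 6 arrays, and GYUW2K401ANRHD was lower (-3.31 ± 0.58). At EC10 and 3 d, contig26698 was at least 3.05-fold and contig08352 3.25-fold (above background on 1 of 3 Gesaprim arrays) higher with nano_ATZ, and GYUW2K402JMOBO and GYUW2K402G9LOS were lower (-2.03 ± 0.39 and -1.84 ± 0.37). A block for slide ended the calls of contig26698 (fitted difference 3.30 ± 0.66 before and 2.32 ± 0.59 after), GYUW2K402JMOBO (-1.94 ± 0.45) and GYUW2K402G9LOS (-1.30 ± 0.37), and at EC50 and 7 d those of contig09971 and GYUW2K402I0D5Q. The fitted differences of these last 2, no bounds since Gesaprim arrays were at background, went from 3.59 ± 0.60 to 3.26 ± 0.63 and from 3.49 ± 0.75 to 3.80 ± 0.87. At EC10 and 7 d, the 2 probes called were higher with nano_ATZ, GYUW2K401B0YKR by 1.91 ± 0.34 and GYUW2K402GM6FK while above background on 2 of 3 nano_ATZ and 1 of 3 Gesaprim arrays. Neither was called with slide as a block (1.84 ± 0.36, adjusted p = 0.228, and 0.763).

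Between nano_ATZ and Gesaprim, 88 probes differed at EC50 and 3 d (64 higher with nano_ATZ, 24 lower), 36 at EC50 and 7 d (19 and 17), 8 at EC10 and 3 d (6 and 2) and 2 at EC10 and 7 d. The balance of the 88 turned to 0 and 2 after normexp and 40 and 72 when scaled on probes above background on all arrays, and with only the arrays of the comparison limma called 0 (3144 at an unadjusted p under 0.05). That of the 36 turned to 21 and 22 after quantile normalization, 25 and 26 with slide as a random block and 1 and 9 with slide as a block. A block for slide made these counts 174, 10, 22 and 0. The first became 8, 50 and 44 without nano_ATZ replicates 1 to 3 and 30, 8 and 241 without Gesaprim replicates 1 to 3. The second became 57, 22 and 12 without nano_ATZ replicates 1 to 3 and 12 and 15 without Gesaprim replicates 1 and 2. The third became 0 without any nano_ATZ array or Gesaprim replicate 1, 5 without Gesaprim replicate 2 and 84 without replicate 3. The fourth became 0, 1 and 51 without nano_ATZ replicates 1 to 3 and 1, 4 and 0 without Gesaprim replicates 1 to 3. For contig08852 the difference at EC50 was 0.78 (95% interval -0.06 to 1.61, adjusted p = 0.379) at 3 d and 0.65 (-0.18 to 1.49) at 7 d, so a difference of that size was not excluded.

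Each formulation's change was also compared with the change by ATZ, each against its own control. At EC50 and 7 d, the log2 change of contig08244 was 2.04 with nano_ATZ and -0.61 with ATZ (difference 2.64 ± 0.49), and that of contig17390 was -2.75 and 0.12 (difference -2.88 ± 0.54). The other 2 of the 4 probes called, contig13023 and contig10344 (the latter named after its value was seen), had a negative difference, but no nano_ATZ EC50 array was above background for either, and no acetone control array for contig13023, so no size is given. Limma called 0 with slide as a block (1464 at an unadjusted p under 0.05), though the differences of contig08244 (2.71 ± 0.53) and contig17390 (-2.98 ± 0.55) did not shrink and their SEs grew. With Gesaprim at EC50 and 3 d, 6 probes were called, all with a negative difference (Gesaprim change minus ATZ change). The first 2, contig13977 and contig01494, were above background on 0 of 3 Gesaprim EC50 arrays and 1 of 3 acetone control arrays, so no size is given. With slide as a block limma called 0, with 1292 at an unadjusted p under 0.05. Limma called 0 probes for nano_ATZ at EC10 and 3 d, EC50 and 3 d and EC10 and 7 d, with 799, 1844 and 1955 at an unadjusted p under 0.05, and 0 for Gesaprim at EC10 and 3 d, EC10 and 7 d and EC50 and 7 d, with 904, 2211 and 241. The log2 change of GYUW2K401EB6BI at EC50 and 3 d was -0.94 with Gesaprim and -5.50 with ATZ, and the difference of 4.57 (95% interval 2.37 to 6.77) did not pass the test (adjusted p = 0.125). The same difference was smaller at EC50 and 7 d (2.87 ± 1.08) and at EC10 (2.86 ± 1.08 at 3 d, 1.54 ± 1.08 at 7 d), and was not called there.

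The counts of these differences moved with single arrays. The 6 for Gesaprim at EC50 and 3 d became 143 without Gesaprim replicate 3, 23 without acetone control replicate 2, 3 without acetone control replicate 1 or control replicate 2, and 0 without control replicates 1 or 3, acetone control replicate 3, ATZ replicates 1 or 3 or Gesaprim replicates 1 or 2. The 4 for nano_ATZ at EC50 and 7 d became 2 without nano_ATZ replicate 1 or ATZ replicate 2, and 0 without any control array, acetone control replicates 2 or 3, nano_ATZ replicates 2 or 3 or ATZ replicate 3. Where 0 had been called at 3 d, nano_ATZ at EC10 gave 1 and 2 without acetone control replicates 1 and 2, Gesaprim at EC10 gave 1 without acetone control replicate 2, and nano_ATZ at EC50 gave 2 and 6 without acetone control replicates 1 and 2 and 1 without nano_ATZ replicate 3. At EC10 and 7 d, leaving out ATZ replicate 3 gave 1 for nano_ATZ and 2 for Gesaprim.

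Concentration was tested as EC50 against EC10 within a material, averaged over days. With nano_ATZ, contig17320 was higher at EC50 by 3.09 ± 0.48 (8.54-fold, adjusted p = 0.00527), going from 0.78 ± 0.24 (SD) to 4.48 ± 1.0 at 3 d and from 0.42 ± 1.14 to 2.91 ± 0.58 at 7 d. With slide as a block it differed by 3.37 (adjusted p = 0.0312). The call was lost after normexp (1.83, adjusted p = 0.121), when only the arrays of the comparison were fitted (3.09, adjusted p = 0.192) and without nano_ATZ EC50 replicate 2 of 3 d (2.81, adjusted p = 0.0613). In the same comparison contig08244 was higher by 1.39 ± 0.24, and contig19147 (above background on 0 of 3 EC50 arrays at 3 d and 1 of 3 at 7 d, so no size is given), GYUW2K401EB6BI (-2.83 ± 0.54) and GYUW2K401B0YKR (-1.27 ± 0.24, named after its value was seen) were lower. These were the 5 probes called, and with slide as a block 1 was, while contig08244 (1.45 ± 0.27), GYUW2K401EB6BI (-3.09 ± 0.61) and GYUW2K401B0YKR (-1.44) differed by at least as much as before. Limma called 0 for Gesaprim and 0 for ATZ, with 1409 and 2055 at an unadjusted p under 0.05. For contig17320 the difference was 0.59 (95% interval -0.39 to 1.57) with Gesaprim and 1.54 (0.56 to 2.52, adjusted p = 0.454) with ATZ. Whether these differ from that with nano_ATZ was not tested.

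The nano_ATZ count of 5 fell to 2, 1, 1, 0 and 2 without EC10 replicates 1 and 2 and EC50 replicates 1, 2 and 3 at 3 d, and to 1, 3, 1, 3 and 1 without EC10 replicates 1, 2 and 3 and EC50 replicates 2 and 3 at 7 d. For ATZ, the count became 12 without EC10 replicate 3 at 3 d, 15 and 1 without EC50 replicates 1 and 3 at 7 d and 1 without EC10 replicate 3 at 7 d. For Gesaprim it became 9 without EC10 replicate 3 and 2 without EC50 replicate 1 or 3, all at 3 d.

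Time was tested as the change at 7 d against that at 3 d. Limma called 0 probes for each of nano_ATZ, Gesaprim and ATZ, with 856, 2682 and 1364 at an unadjusted p under 0.05. For contig08852 the differences were -0.64 (95% interval -1.69 to 0.40), -0.61 (-1.63 to 0.41) and 0.49 (-0.54 to 1.51). Without control replicate 2 at 7 d, Gesaprim gave 2, and ATZ gave 1 and 2 without acetone control replicates 1 and 2 at 3 d. The comparisons at 3 and 7 d share no array. In nano_ATZ EC10 and EC50, 29 and 69 probes were called in the same direction at both days. These numbers were 25 and 27 for Gesaprim and 55 and 101 for ATZ. At most 3.83 were expected from the counts with probes taken as independent, and 0 were called in opposite directions.

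Arrays also differed by replicate number, slide and scan day, which the groups do not name. The first principal component held 29.1% of the variance, of which day accounted for 25.6% (permutation p = 3e-04, adjusted over 15 tests 0.0015) and replicate number for 27.4% (0.0011, adjusted 0.00413). Group accounted for 46.8% of it and did not pass (permutation p = 0.0661, adjusted 0.110). On the second component, which held 11.8%, group accounted for 57.5% (permutation p = 0.0071, adjusted 0.0213) and slide for 44.8% (0.0136, adjusted 0.027). Scan day accounted for 25.2% of it (permutation p = 0.0144, adjusted 0.027). Slide accounted for 80.8% of the third component, which held 10.1% (permutation p = 1e-04, the smallest the permutations can give). Scan day accounted for 61.3% of it (permutation p = 1e-04). Each slide was scanned on 1 day, and slide 6 was the only slide of its scan day, so their parts cannot be told apart there. Each slide held 3 or 4 groups, and 9 of the 12 held both days. Slide 7 had the fewest probes above background, between 13137 and 14185, and slide 11 a mean of 129.75 outlier spots per array.

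**Figure D4:**
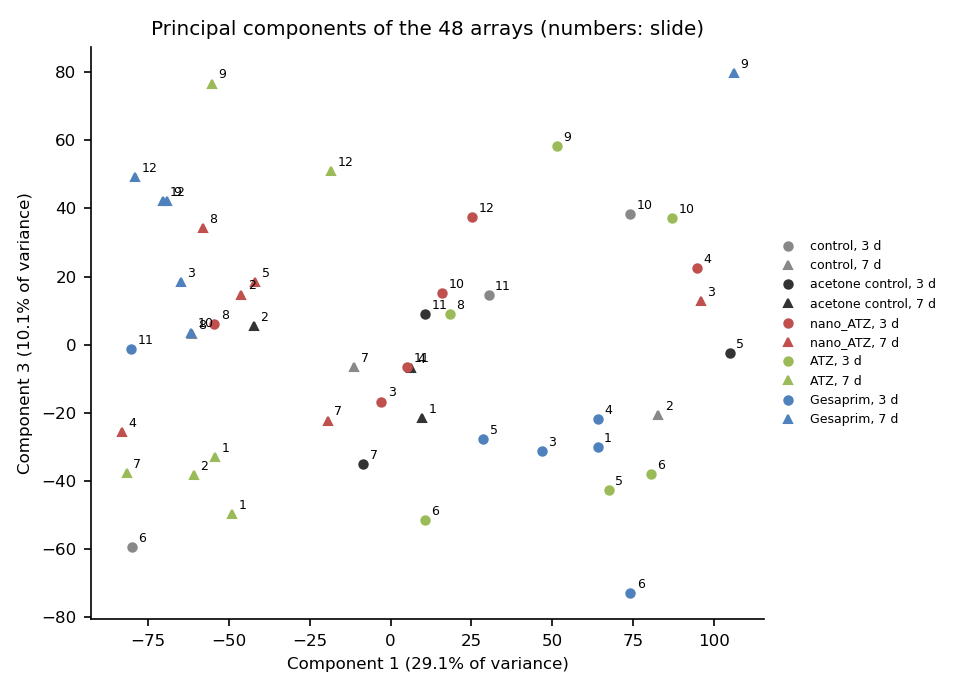
Principal components 1 and 3 of the 48 arrays (x and y axes, 29.1% and 10.1% of the variance). Each point is an array, coloured by exposure, shaped by day and numbered by slide, and slide accounted for 80.8% of component 3.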

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

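Of the tests in this part, those of the arrays of other groups on slide 6 and of the median at 7 d were chosen before the result was seen, and the counts of splits and all other tests after. A test of the difference between materials picked out 6 results. Between nano_ATZ and Gesaprim, 8 probes differed at EC10 and 3 d, 88 at EC50 and 3 d, 2 at EC10 and 7 d and 36 at EC50 and 7 d. The change by Gesaprim differed from that by ATZ in 6 probes at EC50 and 3 d, and the change by nano_ATZ from that by ATZ in 4 at EC50 and 7 d.

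The 821 probes called with ATZ EC50 at 3 d, with a median change of 1.22 log2 units, are a pattern that slide and group share in part. Without acetone control replicate 1, on the dim slide 7, 749 probes were called, which argues against that array as the cause, but without replicate 3, which lay -0.42 from the other 2 in the called direction, 189 were (163 without ATZ replicate 3), while the median against the other 2 was 1.02, so its part in the count stays open. Arrays of other groups on slide 6, which held 2 of the 3 ATZ EC50 arrays, lay 0.273 from the rest of their groups in the called direction (control 0.13, Gesaprim EC50 0.41), and the bound set beforehand against a slide effect was met by that mean but not by the second array, so the test was read, after its result was seen, as deciding nothing. Over the 967 probes called without the ATZ EC50 array of slide 9, that array lay 0.57 from un-spiked control arrays outside slide 6 in the called direction (90.6% of probes), beside 1.16 for the slide 6 arrays, just short of the bound set for excluding slide 6 as the whole cause. At 7 d, on other arrays, the same probes had a median change of 0.563 in the same direction (96.0% of them), between the bounds set beforehand.

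Of the 821 probes, 101 were called in the same direction at 7 d, on other arrays, none on slide 6, though slide 9 held an ATZ EC50 array at both days. Their median change at 3 d was 1.99, and 1.86 with slide as a block, where 100 of the 101 changed by over 2 SEs. The same 3 d arrays had chosen these probes, which favours that count, and the block adjusts only through other groups. That the median shrank so little goes against a slide effect as the whole cause for them but does not exclude it. With larger SEs only 41 stayed called. For the other 720, whose median went from 1.15 to 0.97, 602 changed by over 2 SEs with the block, short of the bound of 9 in 10, and 19 stayed called. A slide effect, acetone control replicate 3 and a response to ATZ cannot be told apart for these 720, because no slide held both groups and only 2 other arrays were on slide 6. Since slide 6 was also the only slide of its scan day, an effect of that slide includes any of its scan day.

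GYUW2K401EB6BI was called as a fall in 6 of the 12 exposures, among them nano_ATZ EC50 at both days and ATZ EC50 at 3 d. With ATZ EC50 at 7 d it stood at 3.39 ± 1.57 (SD), beside 7.22 ± 0.68 in acetone control. Its level with nano_ATZ EC50 was below that with Gesaprim EC50 at both days. With slide as a block the difference between nano_ATZ EC50 and Gesaprim EC50 was -6.06 at 3 d and -5.78 at 7 d. At 3 d, 1 slide held both groups (-6.79 within it), so the values there go against a slide effect as the cause. At 7 d no slide held both, so the block adjusts only through other groups. With any array left out the smallest difference was -5.04, against a single array as the cause. All 48 of its spots were well above background and unmarked, against dim spots. Over the alternatives that keep every array or leave out slide 7, the difference lay between -6.06 and -4.77 at 3 d (adjusted p between 1.18e-04 and 0.0866, not called with only the arrays of the comparison) and between -5.81 and -4.99 at 7 d. A difference between the materials may explain it, a hypothesis found in these data, while the mass given and cross-hybridization were not tested.

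Other splits of the same arrays were counted, with the real split included. Where 3 arrays stood against 3 there were 10 splits, too few for a share under 0.05. At 3 d, 1 split gave as many probes for nano_ATZ EC10 (67, highest other 1), nano_ATZ EC50 (161, 0), Gesaprim EC10 (82, 1), Gesaprim EC50 (85, 2), ATZ EC10 (86, 1) and ATZ EC50 (821, 4). At 7 d, 1 did for nano_ATZ EC50 (236, 0), Gesaprim EC10 (70, 1), Gesaprim EC50 (69, 0), ATZ EC10 (211, 3) and ATZ EC50 (160, 0), and 2 for nano_ATZ EC10 (52, 265). For acetone 2 did at 3 d (1, highest other 1), and at 7 d, where 0 were called, all 10 by construction (highest other 0). Between nano_ATZ and Gesaprim, 1 did at EC10 and 3 d (8, 1), EC50 and 3 d (88, 2) and EC50 and 7 d (36, 0), and 4 at EC10 and 7 d (2, 930). The splits with 265 and 930 point to a structure of the samples, as they part the arrays along component 1 by 92.9 and 121, beside 6.80 and 19.9 for the real splits.

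For the other comparisons 100 splits were drawn. For Gesaprim against ATZ at EC50 and 3 d, 4 gave as many as the 6 called. This share is under 0.05 only without adjustment for the number of comparisons split, so chance was not excluded. The highest other split gave 909. That split follows slide 6: it puts both ATZ EC50 arrays and the Gesaprim EC50 array of that slide in 1 exposed group. The slide's control array falls in the control of the other exposed group. All arrays of slide 6 therefore enter the difference of differences with the same sign. Limma called 0 with slide as a block (1292 at an unadjusted p under 0.05). For EC50 against EC10 with nano_ATZ, 2 gave as many as the 5 called (highest other 5), again a share without that adjustment. The splits take no account of slide, and with slide as a block 1 probe was called, so chance was not excluded. For nano_ATZ against ATZ at EC50 and 7 d, 5 gave as many as the 4 called (highest other 7), and chance was not excluded. Where 0 were called, all 100 gave as many by construction, which says nothing about chance. There the highest others were 1 (nano_ATZ EC10), 1575 (Gesaprim EC10) and 1048 (nano_ATZ EC50) for changes against ATZ at 3 d, and 57 (nano_ATZ EC10), 0 (Gesaprim EC10) and 1 (Gesaprim EC50) at 7 d. For EC50 against EC10 they were 17 (Gesaprim) and 1006 (ATZ), and for 7 d against 3 d 472 (nano_ATZ), 1078 (Gesaprim) and 213 (ATZ). Splits that call so many probes point to a structure of the samples beyond the groups.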

How the results depend on the processing

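The 75th percentile over probes above background on all arrays, slide as a random block and leaving out slide 7 were chosen after seeing the data, and the other alternatives before. A count is given where it moved by more than 1.5-fold, and the cause was not tested except where stated. No change of a named probe reversed under any alternative run. Of the 72 named changes, the number no longer called was 25 after normexp correction, 12 after quantile normalization, 17 with no filter, 22 with a slide block, 6 with a replicate block and 33 with only the arrays of the comparison. It was 5 with the other percentile, 14 without slide 7 and 0 with the random block, the deposited values or, for the 31 that could be tested, the stricter filter. The deposited values tested rounding alone, and 0 of their 34 counts moved. With an array left out, 344 of 486 values of named probes stayed called and 142 did not.

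After normexp background correction, the moved exposure counts were at 3 d 21 (nano_ATZ EC10), 46 (nano_ATZ EC50), 13 (Gesaprim EC10), 19 (Gesaprim EC50), 39 (ATZ EC10) and 74 (ATZ EC50), and at 7 d 18 (nano_ATZ EC10), 75 (nano_ATZ EC50), 16 (Gesaprim EC10), 35 (Gesaprim EC50), 100 (ATZ EC10) and 52 (ATZ EC50). Normexp gave 2 (EC50, 3 d), 0 (EC10, 7 d) and 15 (EC50, 7 d) between nano_ATZ and Gesaprim, 5 (nano_ATZ EC10, 3 d), 0 (Gesaprim EC50, 3 d) and 0 (nano_ATZ EC50, 7 d) for a change against that of ATZ, 1 (ATZ) for 7 d against 3 d, 2 for acetone at 3 d, a median overlap of 14 and 4 common probes. After quantile normalization, the moved exposure counts were at 3 d 45 (Gesaprim EC10), 181 (Gesaprim EC50) and 496 (ATZ EC50), and at 7 d 370 (ATZ EC10). Quantile normalization gave 1 (EC10, 3 d) and 5 (EC10, 7 d) between nano_ATZ and Gesaprim, 2 (Gesaprim EC50, 3 d) and 1 (nano_ATZ EC50, 7 d) for a change against that of ATZ, 1 (ATZ) for 7 d against 3 d and 2 for acetone at 3 d. Scaled on the 75th percentile over the probes above background on all arrays, the moved exposure counts were at 3 d 443 (ATZ EC50). This scaling gave 45 (EC10, 3 d) and 5 (EC10, 7 d) between nano_ATZ and Gesaprim, 2 (nano_ATZ EC50, 3 d) and 0 (Gesaprim EC50, 3 d) for a change against that of ATZ, 3 (nano_ATZ) and 1 (ATZ) for EC50 against EC10 and 2 for acetone at 3 d.

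These scalings moved the median of all tested probes, by up to 0.34 log2 units for the other percentile (Gesaprim against ATZ at EC50 and 3 d), 0.20 for normexp (nano_ATZ against Gesaprim at EC50 and 7 d) and 0.06 for quantile normalization. They also changed the balance of rises and falls. Normexp gave rises and falls at 3 d of 10 and 11 (nano_ATZ EC10, before 45 and 22), 15 and 31 (nano_ATZ EC50, before 122 and 39), 9 and 4 (Gesaprim EC10, before 44 and 38), 21 and 18 (ATZ EC10, before 62 and 24) and 57 and 17 (ATZ EC50, before 738 and 83). At 7 d it gave 7 and 11 (nano_ATZ EC10, before 34 and 18), 17 and 18 (Gesaprim EC50, before 47 and 22), 27 and 73 (ATZ EC10, before 112 and 99) and 30 and 22 (ATZ EC50, before 120 and 40). Between nano_ATZ and Gesaprim at EC50 it gave 0 and 2 (3 d, before 64 and 24) and 10 and 5 (7 d, before 19 and 17). Quantile normalization gave 35 and 10 (Gesaprim EC10, 3 d), 96 and 85 (Gesaprim EC50, 3 d, before 55 and 30), 148 and 222 (ATZ EC10, 7 d), 1 and 0 (nano_ATZ against Gesaprim, EC10, 3 d, before 6 and 2), 0 and 1 (nano_ATZ against ATZ, EC50, 7 d, before 1 and 3) and 3 and 2 (nano_ATZ EC50 against EC10, before 2 and 3). The other percentile gave, at 3 d, 42 and 70 (Gesaprim EC10), 102 and 22 (Gesaprim EC50), 56 and 40 (ATZ EC10) and 309 rises among 443 (ATZ EC50). Between nano_ATZ and Gesaprim it gave 42 and 3 (EC10, 3 d), 40 and 72 (EC50, 3 d) and 4 and 1 (EC10, 7 d, before 2 and 0), and for nano_ATZ EC50 against EC10 2 and 1.

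With no filter, the moved exposure counts were at 3 d 41 (nano_ATZ EC10), 89 (nano_ATZ EC50), 35 (Gesaprim EC10), 159 (Gesaprim EC50) and 337 (ATZ EC50), and at 7 d 122 (nano_ATZ EC50), 40 (Gesaprim EC10) and 121 (ATZ EC10). No filter gave 0 (EC10, 3 d), 24 (EC50, 3 d) and 0 (EC10, 7 d) between nano_ATZ and Gesaprim, 0 (Gesaprim EC50, 3 d) and 0 (nano_ATZ EC50, 7 d) for a change against that of ATZ, 1 (nano_ATZ) for EC50 against EC10 and 2 for acetone at 3 d. With only probes above background on all 48 arrays, the moved exposure counts were at 3 d 40 (Gesaprim EC10) and 40 (Gesaprim EC50), and at 7 d 32 (nano_ATZ EC10). The stricter filter gave 252 (EC50, 3 d), 5 (EC10, 7 d) and 69 (EC50, 7 d) between nano_ATZ and Gesaprim, 1 (nano_ATZ EC50, 7 d) for a change against that of ATZ, 2 (nano_ATZ) for EC50 against EC10, a median overlap of 25 and 9 common probes. These 2 alternatives tested different numbers of probes, 43750 and 10676 in place of 24011, which by itself changes the adjustment.

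With a block for slide, the moved exposure counts were at 3 d 41 (nano_ATZ EC10), 36 (Gesaprim EC50) and 63 (ATZ EC50), and at 7 d 533 (nano_ATZ EC50), 14 (Gesaprim EC10), 28 (Gesaprim EC50), 1.3e2 (ATZ EC10, 82 rises and 52 falls) and 76 (ATZ EC50). The slide block gave 22 (EC10, 3 d), 174 (EC50, 3 d), 0 (EC10, 7 d) and 10 (EC50, 7 d) between nano_ATZ and Gesaprim, 1 (nano_ATZ EC10, 3 d), 1 (Gesaprim EC10, 3 d), 0 (Gesaprim EC50, 3 d) and 0 (nano_ATZ EC50, 7 d) for a change against that of ATZ, 1 (nano_ATZ) for EC50 against EC10 and 10 common probes. With slide as a random block, the moved exposure counts were at 7 d 448 (nano_ATZ EC50) and 323 (ATZ EC10). The random block gave 34 (EC10, 3 d), 312 (EC50, 3 d) and 5 (EC10, 7 d) between nano_ATZ and Gesaprim and 2 for acetone at 3 d. The random block used a correlation of 0.158 within slides. With a block for replicate number, the moved exposure counts were at 3 d 153 (Gesaprim EC50), and at 7 d 446 (nano_ATZ EC50) and 474 (ATZ EC10). The replicate block gave 1 (EC10, 3 d), 207 (EC50, 3 d) and 4 (EC10, 7 d) between nano_ATZ and Gesaprim, 4 (nano_ATZ EC50, 3 d) for a change against that of ATZ, 3 (nano_ATZ) for EC50 against EC10 and 1 (ATZ) for 7 d against 3 d. The labels do not say that the replicate numbers pair the samples, and not every pair of the same number correlated above 0.1. Arrays of the same number and day correlated at a mean of 0.110, after removal of group means, and those of different numbers at -0.0550. Of 168 pairs of the same number, 89 were above 0.1, and 32 of 48 arrays were closest to their own number, a hint from the data alone. In 2 comparisons, ATZ EC50 at 3 d and Gesaprim EC10 at 7 d, all 3 numbers were above 0.1, and the replicate block made their counts 1022 and 84, beside 821 and 70.

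Without the 4 arrays of slide 7, the moved exposure counts were at 7 d 28 (nano_ATZ EC10), 116 (nano_ATZ EC50), 40 (Gesaprim EC10), 38 (Gesaprim EC50) and 75 (ATZ EC10). Leaving out slide 7 gave 18 (EC10, 3 d) and 0 (EC10, 7 d) between nano_ATZ and Gesaprim, 1 (nano_ATZ EC10, 3 d), 2 (nano_ATZ EC50, 3 d), 3 (Gesaprim EC50, 3 d) and 0 (nano_ATZ EC50, 7 d) for a change against that of ATZ, 1 (nano_ATZ) for EC50 against EC10, 1 (ATZ) for 7 d against 3 d and 2 for acetone at 3 d. Fitting only the arrays of each comparison, the moved exposure counts were at 3 d 8 (nano_ATZ EC10), 17 (nano_ATZ EC50), 2 (Gesaprim EC10), 5 (Gesaprim EC50), 17 (ATZ EC10) and 22 (ATZ EC50), and at 7 d 2 (nano_ATZ EC10), 34 (nano_ATZ EC50), 1 (Gesaprim EC10), 7 (Gesaprim EC50), 352 (ATZ EC10) and 77 (ATZ EC50). This narrower fit gave 0 (EC10, 3 d), 0 (EC50, 3 d) and 0 (EC10, 7 d) between nano_ATZ and Gesaprim, 0 (Gesaprim EC50, 3 d) and 0 (nano_ATZ EC50, 7 d) for a change against that of ATZ, 0 (nano_ATZ) for EC50 against EC10 and 0 for acetone at 3 d. A fit of only those arrays has fewer residual degrees of freedom.

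Leaving out each array in turn gave exposure counts at 3 d of 34 to 45 (nano_ATZ EC10), 73 to 104 (nano_ATZ EC50), 23 to 424 (Gesaprim EC10), 33 to 204 (Gesaprim EC50), 49 to 99 (ATZ EC10) and 163 to 967 (ATZ EC50), and at 7 d of 91 to 241 (nano_ATZ EC50), 37 to 77 (Gesaprim EC10), 33 to 109 (Gesaprim EC50), 73 to 306 (ATZ EC10) and 72 to 202 (ATZ EC50). Between nano_ATZ and Gesaprim these ranges were 0 to 84 (EC10, 3 d), 8 to 241 (EC50, 3 d), 0 to 51 (EC10, 7 d) and 12 to 57 (EC50, 7 d), and for a change against that of ATZ 0 to 2 (nano_ATZ EC10, 3 d), 0 to 1 (Gesaprim EC10, 3 d), 0 to 6 (nano_ATZ EC50, 3 d), 0 to 143 (Gesaprim EC50, 3 d), 0 to 1 (nano_ATZ EC10, 7 d), 0 to 2 (Gesaprim EC10, 7 d) and 0 to 4 (nano_ATZ EC50, 7 d). They were 0 to 4 (nano_ATZ), 0 to 15 (ATZ) and 0 to 9 (Gesaprim) for EC50 against EC10, 0 to 2 (Gesaprim) and 0 to 2 (ATZ) for 7 d against 3 d and 0 to 6 for acetone at 3 d. The median overlap ranged from 29.5 to 46 and the common probes from 14 to 19. Where limma called 0 with an array left out, between 198 and 3616 probes had an unadjusted p under 0.05, and under the other alternatives between 63 and 7874.

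The tests of gene lists and their alternatives were not run, since the files give no gene names, and normexp used the median signal because the mean was not exported. Signal over background limits what can be seen. Between 30.0 and 61.8% of the probes of an array were well above background, so a change of a dimmer probe can be missed. A fall to background is a lower bound under the main processing only, since its size moved with the alternatives.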

Other observations

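All tests in this part were chosen after the results were seen. Probes called in the same direction in at least 2 of the 4 nano_ATZ and Gesaprim comparisons of a day were followed in ATZ, which shares no array with them. At 3 d, 57 such probes rose (median 1.77 log2 units), and their median in ATZ was 2.01, with 57 in the same direction and 34 called in both ATZ comparisons (camera with estimated correlation, adjusted p = 8.60e-10). The 15 that fell (-2.42) had a median of -1.61 in ATZ, with 15 in the same direction and 7 called (adjusted p = 1.06e-09). At 7 d, 52 rose (2.01), with a median of 2.24 in ATZ, 52 in the same direction and 35 called (adjusted p = 7.79e-12), and 28 fell (-1.75), with -1.39, 27 and 12 (adjusted p = 1.03e-07).

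Of the 18 probes called in all 12 exposures, those above background at EC10 or EC50 were compared between these. With nano_ATZ, 17 of 17 lay further from control at EC50 than at EC10 at 3 d (median difference 0.97 log2 units) and 15 of 17 at 7 d (0.44). The numbers were 7 of 17 (-0.06) and 14 of 17 (0.22) for Gesaprim, and 16 of 17 (0.42) and 9 of 16 (0.25) for ATZ. These probes were read on the same 3 arrays per group and are not independent replicates. Neither the numbers nor their difference between materials was tested.

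A hypothesis is that the 3 materials share a response that holds from 3 to 7 d. The shared un-spiked control arrays would forbid a change of the same size in ATZ against acetone control, yet the smaller median there over the 2 days was 1.97, beside 1.83 (72 probes, 3 d) and 1.92 (80 probes, 7 d) in their own comparisons. Of 77 probes called in at least 3 of the 6 exposures at 3 d, 76 kept their direction at 7 d, on other arrays, with a median of 1.73 beside 1.80, and 47 were called in at least 3 exposures there. A response to atrazine itself may explain this, but the formulations' other ingredients were not tested alone.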
